A study of Macaca mulatta with 30 samples.

How the data were processed

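The data were gene expression values of frozen post-mortem cortex from 5 rhesus macaques, measured on 30 Affymetrix arrays. Each animal gave 3 regions from both hemispheres, so that each of the 6 combinations of region and hemisphere held 5 arrays, 1 per animal. The deposited values are log2 intensities that the authors computed by RMA (background correction, quantile normalization and summary to 1 value per probe set) with the oligo package. Per the labels, no version of that package was given, and it was not stated whether the 30 arrays were normalized together with others. The table held 40489 probe sets with values from 1.85 to 13.97, and the medians of the 30 arrays lay between 6.57 and 6.64. Arrays give no read depth; the number of animals limits the precision.

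Gene names came from the platform annotation. Of all probe sets, 16020 (39.6%) had 1 gene symbol, 490 (1.21%) had several and 23979 (59.2%) were not listed. Of 15045 single-symbol probe sets with a gene identifier, 14947 were found in the reference gene table, which changed 0 symbols. The genome build behind the array was not named, so no coordinates are given. No column marks control probe sets, so the planned step of leaving them out could not be carried out. Probe sets whose mean over the 30 arrays lay above the 40th percentile (6.04 on the log2 scale) were tested, which left 24292 probe sets and 11443 distinct gene symbols. Of the tested probe sets, 2037 had values identical to an earlier one to 9 decimals.

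Tests used limma 3.58.1 in R 4.3.3, with tables read by the data.table package (version 1.17.8). For each region, the left minus right difference within each animal was taken and the 15 differences were fitted with 1 mean per region and a shared spread (12 residual degrees of freedom). For all regions together, each animal's differences were first averaged (4 degrees of freedom). The hemisphere by region interaction was a moderated F test with 2 degrees of freedom on the same 15 differences. For region comparisons, both hemispheres were averaged to 15 values and animal entered as block (8 degrees of freedom). P-values were two-sided where a direction exists and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Errors given with log2 differences are moderated standard errors from limma, with n = 5 animals.

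Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, and again with an estimated correlation, with 1 probe set per gene (the brightest). P-values were adjusted over the lists of a comparison. Of 29 lists, 27 had at least 3 measured genes. They covered cell types (excitatory neurons, inhibitory interneurons, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, vascular cells, meningeal and choroid plexus cells, blood), cortical layers (upper and deep) and large-axon and fast-firing neurons. Further lists covered glutamate receptors, GABA receptors, monoamine and acetylcholine receptors, synaptic vesicle release, postsynaptic scaffold, ion channels (potassium, sodium and calcium), neuropeptides, axon guidance and cortical area patterning. The others were immediate early genes, heat shock and hypoxia response, the mitochondrial respiratory chain, ribosomal proteins, interferon response, genes asymmetric in human fetal cortex, left-right body patterning and language-associated genes. Members past 0.05 were counted over all tested probe sets and adjusted over the list alone.

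Named genes follow a rule. In region comparisons they are up to 12 higher and 12 lower genes with the largest log2 difference among those at adjusted p under 0.05 with the same direction in 5 of 5 animals. Only probe sets with 1 non-systematic gene symbol qualify, and only the brightest per gene. In hemisphere comparisons the same rule holds, and where fewer than 10 genes meet it, the genes with the smallest p (10 for all regions, 5 per region) are given as values. For the interaction the 3 genes with the smallest p are given as values. Up to 4 members with the smallest p are named for a list past the threshold, and the measured genes asymmetric in human fetal cortex, FOXP2 and CNTNAP2 are named in the hemisphere comparisons. The comparisons, tests, gene lists, this rule and all but 3 of the other settings were fixed before the data were examined.

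Whether arrays of 1 animal resemble each other was checked by correlating, over the tested probe sets, each array's deviations from the means of its group. Labelled sex was checked with EIF1AY and with the pair of unnamed probe sets that best separated animals 1 and 2 from animal 5. The plan named XIST and several Y-linked genes for this check. Of these EIF1AY alone is reported, and the unnamed pair was picked from these data. Shares of variance are sums of squares of the balanced design as percent of the total, given as the median over probe sets, with a jackknife standard error over animals. The fits were tested on simulated data with the same design, 24292 independent probe sets and 50 changed ones at each size. A log2 difference of 0.5 was recovered for 80% to 94% of changed probe sets in the hemisphere and region comparisons and for 40% in the interaction, and a difference of 0.25 for 18% to 38% and 4%. Unchanged probe sets gave 4 to 11 false calls per comparison. In data simulated the same way, camera called the 1 shifted list and 0 of 26 others (at adjusted p). Since the simulated probe sets were independent, this does not test false list calls where genes vary together. In the real data the estimated correlation reached 0.835, for oligodendrocyte and myelin genes in the hemisphere comparisons within regions.

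The fits were repeated with no animal block, no filter, a filter at the 60th percentile, repeated quantile normalization, eBayes with trend and robust, and the mean of the oligodendrocyte and myelin list as covariate. They were also repeated with 1 probe set per gene, the arrays of 1 region or of 1 hemisphere alone, all pairs in place of means per animal, the mean of all probe sets of a gene for lists, and leaving out each animal in turn. Leaving out 2 or 4 arrays, and counting identical probe sets a single time, were chosen after seeing the data. All 30 arrays were kept as labelled in the leading values.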

Results

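Expression was measured in 3 cortical regions of both hemispheres in 5 rhesus macaques. The regions were ventrolateral prefrontal cortex (VFC, the counterpart of human area 44), superior temporal cortex towards its posterior end (STC, the counterpart of Wernicke's area) and the forelimb part of primary motor cortex (M1C). Animals 1, 2 and 3 were female, of 7.3, 5.5 and 8.6 years, and animals 4 and 5 male, of 4.2 and 2 years. Sex and age therefore go together with animal and were not tested. Each combination of region and hemisphere held 5 arrays.

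Arrays of 1 animal resembled each other. Deviations from the group means correlated across probe sets with a median r of 0.32 for the 75 pairs of arrays from the same animal. For pairs that differed in both animal and group it was -0.082. Deviations are centred within each group of 5 animals, so a positive r within animals makes that between animals negative. Probe sets are not independent replicates, and these r values carry no test. By this measure 28 of 30 arrays lay closest to their own animal. The exceptions were the array labelled M1C left of animal 3 (r = -0.077 with animal 3 and 0.293 with animal 4) and that labelled STC right of animal 4 (0.355 with animal 3 and 0.040 with animal 4). The Y-linked gene EIF1AY read 8.34 log2 on the former and 7.25 on the latter, against 6.82 to 7.70 on the 12 arrays of female animals 1 and 2 and 8.30 to 8.53 on the 6 arrays of male animal 5. A pair of unnamed sex-linked probe sets gave the same contrast with the label on both arrays. The arrays labelled STC right of animal 3 and VFC left of animal 4 carried signal of both sexes. By region, the array labelled M1C left of animal 3 lay nearer STC, and that labelled STC right of animal 4 nearer M1C. As labelled, left minus right in these animals thus holds part of an STC minus M1C difference. Values as labelled are therefore followed by values without 2 arrays (M1C left of animal 3, STC right of animal 4) or without all 4.

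**Figure D1:**
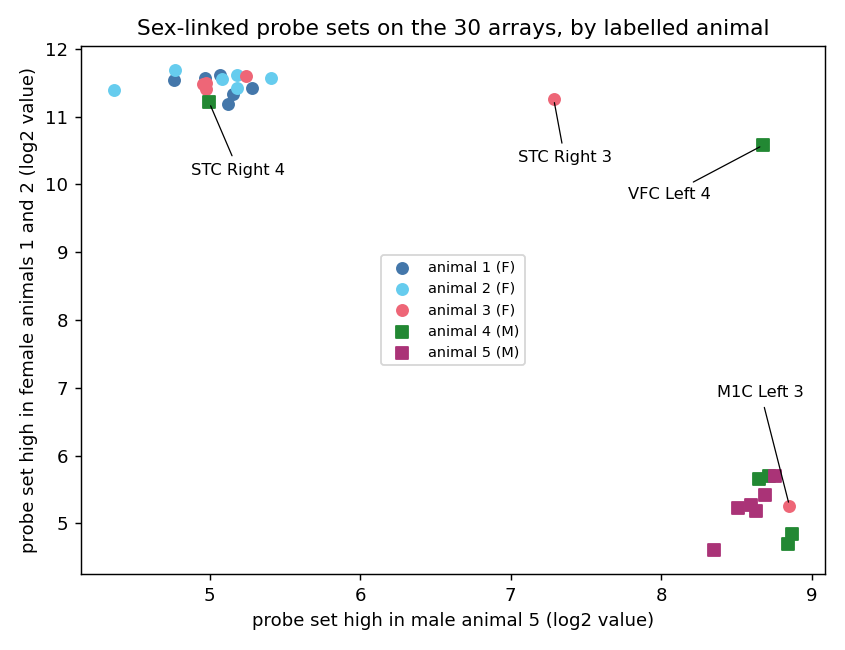
Log2 values of an unnamed probe set high in male animal 5 (horizontal) and one high in female animals 1 and 2 (vertical), 1 point per array (n = 30), coloured by labelled animal, circles female and squares male. The array labelled M1C left of animal 3 lies at 8.85 and 5.26 with the male animals, that labelled STC right of animal 4 at 5.00 and 11.21 with the females, and 2 further arrays are high on both axes.

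The study asks whether expression differs between the hemispheres. Averaged over the 3 regions, the largest evidence for a difference was at SYT10, a synaptotagmin (left minus right 0.40 ± 0.036 log2, 1.32-fold, in 5 of 5 animals, limma adjusted p = 0.0572). CTXN3 (-0.49 ± 0.088, adjusted p = 0.368) and PTGS1, a cyclooxygenase (-0.29 ± 0.047, adjusted p = 0.318), read lower on the left in 5 of 5 animals. None passed the threshold: limma called 0 of 24292 probe sets, with 1608 at an unadjusted p under 0.05 where chance gives 1215. Of the remaining genes with the smallest p, MATN2 (0.23) and SLC24A4 (0.20) read higher and SLC16A6 (-0.30), ADGRG6 (-0.27), MEPE (-0.24), GLRA1 (-0.23) and TPBG (-0.20) lower on the left, each in 5 of 5 animals. The difference of SYT10 was 0.25 ± 0.069 without the 2 arrays (limma adjusted p = 0.824; over all alternatives 0.00335 to 1), that of PTGS1 -0.086, CTXN3 -0.24, SLC16A6 -0.15, ADGRG6 -0.15, GLRA1 -0.11 and SLC24A4 0.10, and limma called 0 probe sets with 1163 at an unadjusted p under 0.05.

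Among the gene lists, deep cortical layers read higher on the left over all regions (median of 17 measured genes 0.11 log2, camera adjusted p = 3.22e-08). This list had adjusted p = 0.319 with an estimated correlation. Its leading members were SEMA3E, a guidance semaphorin (0.46 ± 0.13, in 4 of 5 animals), and the nuclear receptor NR4A2 (0.46 ± 0.095, in 4 of 5); 0 members passed over all genes (unadjusted p under 0.05 for both) and 5 adjusted over the list alone. Large-axon and fast-firing neurons read lower (median of 15 genes -0.11, camera adjusted p = 8.5e-09; adjusted p = 0.319 with an estimated correlation), with SYT2 at -0.26 ± 0.065 in 5 of 5 animals. This median was -0.021 without the 2 arrays (camera adjusted p = 0.36; without the 4 arrays 7.45e-05; over all alternatives 7.59e-09 to 0.36), and SYT2 read -0.034 ± 0.091. That of deep layers was 0.045 without the 2 arrays (camera adjusted p = 7.53e-05), where 2 members passed adjusted over the list alone. Over all alternatives the camera adjusted p of deep layers was 8.08e-12 to 0.319. The STC minus M1C difference, part of which the 2 arrays bring into left minus right, had the same directions as labelled. Its medians were -0.32 for large-axon genes, 0.13 for deep layers and -0.094 for vascular cells. Vascular cells read lower on the left (median -0.091, camera adjusted p = 1.74e-05; adjusted p = 0.319 with an estimated correlation), with a median of -0.050 without the 2 arrays. As labelled, deep layers were also called in M1C and STC but not in VFC (median 0.030, camera adjusted p = 0.221). Without the 4 arrays they were called in STC (camera adjusted p = 0.00592) and VFC (0.0447) but not in M1C (0.234). Whether this list differs between regions in its left minus right difference was not tested. Neuropeptides (median 0.057), glutamate receptors (0.032) and immediate early genes (0.028) read higher and respiratory chain genes (-0.032) lower on the left (camera adjusted p = 0.000954 to 0.0368; adjusted p = 0.319 to adjusted p = 0.431 with an estimated correlation), all lost without the 2 or the 4 arrays. Left-right body patterning genes did not pass (median of 6 genes -0.025, camera adjusted p = 0.416). Some lists passed only without the 2 arrays. These were oligodendrocytes and myelin (median 0.11, camera adjusted p = 0.000883), meningeal and choroid plexus cells (-0.14, 0.00259) and upper layers (-0.032, 0.0369). Each had adjusted p = 0.962 there with an estimated correlation, and without the 4 arrays none of them passed (camera adjusted p = 0.129, 0.344 and 0.348).

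Within VFC, the gene with the smallest p was ZNF274, a zinc finger protein (-0.37 ± 0.071 log2, lower on the left in 5 of 5 animals, limma adjusted p = 0.95). RNF126 (-0.21), SDS (-0.30), KCNK6 (-0.29) and H2BC9 (0.28) followed. An unnamed probe set, 13594888, had the largest evidence (-0.56 ± 0.080, in 5 of 5 animals, limma adjusted p = 0.0688). Without the 2 arrays its adjusted p was 0.218, but neither is a VFC array, so its difference stays the same. Without the 4 arrays, which hold VFC left of animal 4, limma called 0 probe sets in VFC, with 801 at an unadjusted p under 0.05. Limma called 0 probe sets, with 869 at an unadjusted p under 0.05. Oligodendrocyte and myelin genes read higher on the left (median of 19 genes 0.17, camera adjusted p = 0.00027; adjusted p = 0.938 with an estimated correlation), as in MBP (0.20 ± 0.12) and MOBP (0.41 ± 0.25), each in 3 of 5 animals. Without the 4 arrays this list had camera adjusted p = 0.978 (over all alternatives 2.37e-07 to 0.978).

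Within STC, genes typical of the meninges read lower on the left. OGN was -1.07 ± 0.37 log2 and SLC13A4 -1.04 ± 0.33, each lower in 4 of 5 animals, and LUM -0.67 ± 0.22, lower in 5 of 5. The list of meningeal and choroid plexus cells had a median of -0.15 over 11 genes (camera adjusted p = 5.73e-05; adjusted p = 0.318 with an estimated correlation). It had 0 members past the threshold over all genes and 4 adjusted over the list alone. Without the 2 arrays 0 passed adjusted over the list alone, with a median of -0.23. The list stayed called there (camera adjusted p = 2.43e-06, and 0.52 with an estimated correlation) and without the 4 arrays (3.49e-05). Deep-layer genes read higher on the left (median of 17 genes 0.19, camera adjusted p = 6.16e-05, and 0.318 with an estimated correlation), with ADRA2A at 0.19 ± 0.078 in 5 of 5 animals. Without the 2 arrays the deep-layer list stayed called (median 0.16, camera adjusted p = 0.00189, and 0.611 with an estimated correlation). Immediate early genes, which respond to neuronal activity, read higher on the left (median of 16 genes 0.13, camera adjusted p = 5.73e-05; adjusted p = 0.318 with an estimated correlation), with FOS at 0.30 ± 0.098 and NPAS4 at 0.22 ± 0.080 in 5 of 5 animals. Their median was 0.075 without the 2 arrays, and the call was lost without the 4 (camera adjusted p = 0.0519; over all alternatives 2.03e-05 to 0.318). Inhibitory interneurons also read higher (median of 14 genes 0.067, camera adjusted p = 0.00904; adjusted p = 0.318 with an estimated correlation), a call also lost without the 4 arrays (0.0516; over all alternatives 0.00907 to 0.318). Vascular cells (median -0.076, camera adjusted p = 0.004; adjusted p = 0.396 with an estimated correlation) and oligodendrocyte and myelin genes (-0.12, 0.0499; adjusted p = 0.677 with an estimated correlation) read lower on the left. Without the 2 arrays the vascular median was -0.049 (camera adjusted p = 0.0568; without the 4 arrays 0.00592; over all alternatives 0.000413 to 0.396). That of the oligodendrocyte and myelin genes turned to 0.020, and their call was lost. Astrocytes (-0.039), heat shock and hypoxia genes (-0.051) and large-axon and fast-firing neurons (-0.17) also read lower (camera adjusted p = 0.0499, 0.0499 and 0.00345; adjusted p = 0.396, 0.433 and 0.396 with an estimated correlation). Neuropeptides (0.12), excitatory neurons (0.059), monoamine and acetylcholine receptors (0.042) and postsynaptic scaffold (0.038) read higher (camera adjusted p = 0.0148 to 0.0499; adjusted p = 0.396 to adjusted p = 0.469 with an estimated correlation). All 7 calls were lost without the 2 arrays; large-axon genes alone passed without the 4. GJB2, a gap junction protein (-0.62 ± 0.13, in 5 of 5 animals, limma adjusted p = 0.999), had the smallest p of the named genes, ahead of DOHH (0.21), GPR25 (0.21), PLCE1 (-0.19) and HAVCR2 (-0.31). Limma called 0 probe sets, with 1133 at an unadjusted p under 0.05.

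Within M1C, PLPP5 (0.35 ± 0.066 log2) and the syntrophin SNTB1 (0.32 ± 0.062) read higher on the left in 5 of 5 animals (limma adjusted p = 0.39 for both). OLFML2B (0.47 ± 0.10) read higher and ZNF616 (-0.24 ± 0.053) and SNCG, a synuclein (-0.28 ± 0.061), lower on the left in 5 of 5 animals. Limma called 0 probe sets, with 1367 at an unadjusted p under 0.05. Large-axon and fast-firing neurons read lower on the left (median -0.18, camera adjusted p = 8.86e-07; adjusted p = 0.456 with an estimated correlation), a median of -0.043 without the 2 arrays. Oligodendrocyte and myelin genes (median -0.13, camera adjusted p = 0.00232; adjusted p = 0.551 with an estimated correlation) and vascular cells (-0.12, 0.00232; adjusted p = 0.456 with an estimated correlation) read lower there too, with medians of 0.067 (call lost) and -0.079 without the 2 arrays. Deep layers (median 0.13, camera adjusted p = 0.000324) and glutamate receptors (0.072, 0.0491) read higher, and respiratory chain (-0.071, 0.000101) and heat shock and hypoxia genes (-0.067, 0.0304) lower on the left, each with adjusted p = 0.456 with an estimated correlation. Leaving out the 2 arrays, the respiratory chain list alone of these passed, at a median of -0.035, and that of deep layers was 0.076. Limma called 0 probe sets in VFC, STC or M1C without the 2 arrays, with 1045, 1014 and 1398 at an unadjusted p under 0.05.

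Of the genes asymmetric in human fetal cortex, 2 of 6 were measured, too few for a list test. The transcription regulator LMO4 read -0.055 ± 0.037 log2 (lower on the left in 4 of 5 animals, limma adjusted p = 0.87) and NEUROD6 0.027 ± 0.068 (higher in 3 of 5, adjusted p = 0.974) over all regions. The largest single-region value was that of NEUROD6 in STC (0.35 ± 0.14, higher in 4 of 5 animals, limma adjusted p = 0.999), where animal 2 read 1.16 and the others -0.078 to 0.32; leaving out animal 2 gave 0.14 ± 0.12. FOXP2 (0.0097 ± 0.089, in 3 of 5 animals) and CNTNAP2 (-0.0049 ± 0.037, in 4 of 5), both linked to speech and language, had limma adjusted p = 0.992 and 0.991. Leaving out the 2 arrays gave -0.0055 ± 0.074 for NEUROD6, -0.051 ± 0.079 for FOXP2 and -0.035 ± 0.040 for CNTNAP2.

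Whether the left minus right difference varied between regions was tested by the interaction. SNCG read 0.031 ± 0.061 log2 in VFC, 0.18 ± 0.061 in STC and -0.28 ± 0.061 in M1C (F = 14.8, limma adjusted p = 0.995). ANGPT1, an angiopoietin, read -0.22 in STC and 0.27 in M1C, and RIPK4 0.21 in STC and -0.12 in M1C. Limma called 0 probe sets, with 912 at an unadjusted p under 0.05, and 0 without the 2 arrays, with 1092.

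**Figure D2:**
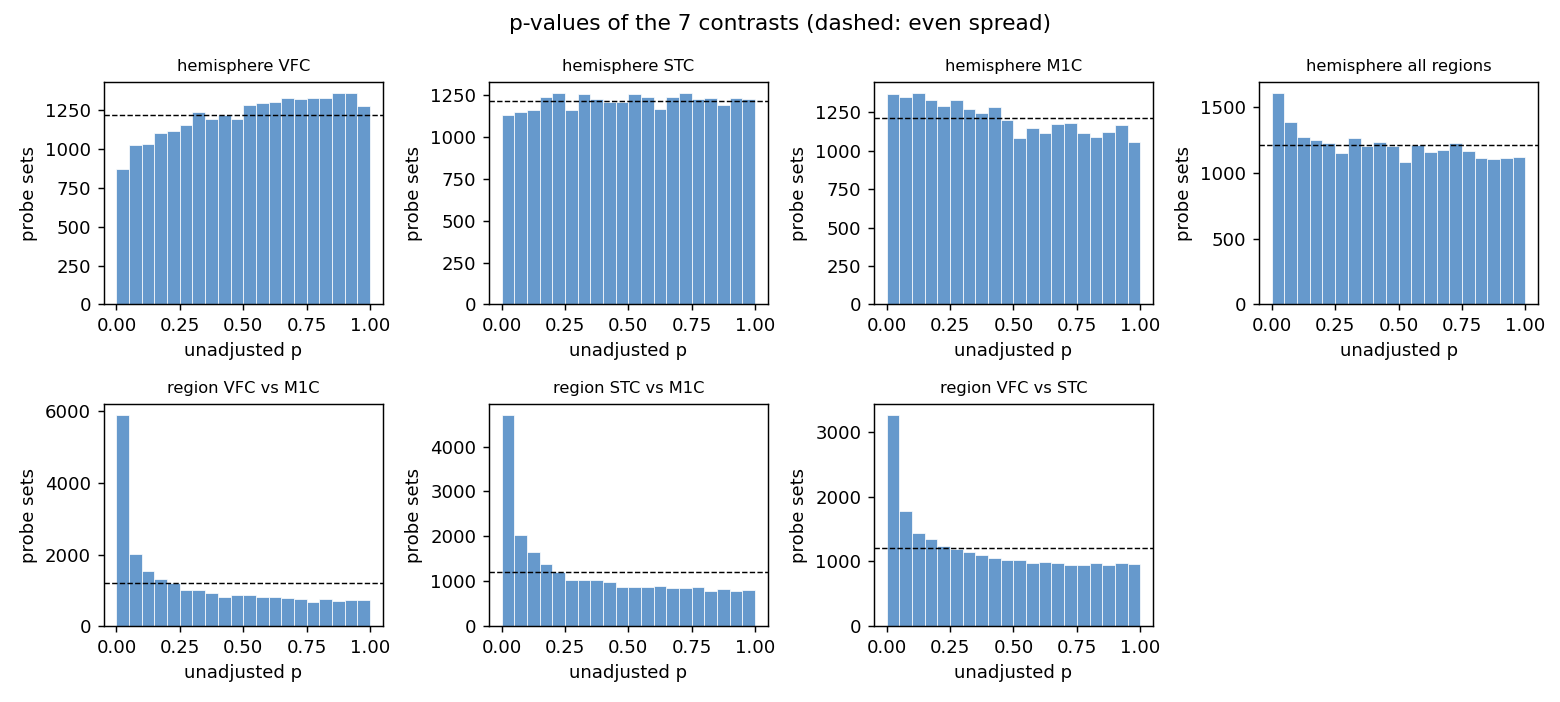
Number of probe sets (vertical) by unadjusted p (horizontal, bins of 0.05) in the 7 left-right and region contrasts, each over 24292 probe sets; the dashed line is an even spread. The lowest bin holds 869 to 1608 probe sets in the hemisphere contrasts and 5907, 4710 and 3267 in the region contrasts VFC vs M1C, STC vs M1C and VFC vs STC.

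VFC and M1C differed in many genes. Of the oligodendrocyte and myelin genes, 16 of 19 were lower in VFC: CNDP1, a carnosinase, read 7.64 ± 0.70 (SD, n = 5) log2 in VFC and 9.29 ± 0.53 in M1C, a 3.15-fold difference (-1.66 ± 0.19, lower in 5 of 5 animals, limma adjusted p = 0.00118). Of the genes of large axons and fast-firing neurons 12 of 15 were lower in VFC, such as the vesicle calcium sensor SYT2 (-1.57 ± 0.20, 2.98-fold, in 5 of 5 animals, adjusted p = 0.0014). Higher in VFC were SYT10 (1.13 ± 0.13, adjusted p = 0.00118; its M1C mean of 5.80 lies below the filter level of 6.04), the glycine receptor subunits GLRA3 (1.09 ± 0.17) and GLRA2 (0.98 ± 0.13), and RBP4, a retinol carrier (0.87 ± 0.092), each in 5 of 5 animals. Limma called 2554 of 24292 probe sets, 1261 higher and 1293 lower in VFC, of which 30 differed at least 2-fold (47 without the 2 arrays, 63 without the 4). Without the 2 arrays there were 3583, 2479 of them among the former.

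Of 19 measured oligodendrocyte and myelin genes, 16 were lower in VFC over all genes and 18 adjusted over the list alone (median -0.88, camera adjusted p = 5.88e-14; adjusted p = 0.208 with an estimated correlation). They included ERMN (-1.24 ± 0.22), MOBP (-1.17 ± 0.24) and UGT8 (-1.12 ± 0.17), which act in myelin or its lipids. Of 15 large-axon and fast-firing genes, 12 were lower and VAT1L (0.26) higher, the same adjusted over the list alone (median -0.54, camera adjusted p = 2.07e-11; adjusted p = 0.208 with an estimated correlation). VAMP1 (-1.19 ± 0.13), SPP1 (-1.21 ± 0.19) and the potassium channels KCNA1 (-0.85 ± 0.097) and KCNC1 (-0.77 ± 0.084) were among them. Of 27 respiratory chain genes, 6 were lower, as ATP5F1A (-0.20 ± 0.052), and 8 adjusted over the list alone (median -0.12, camera adjusted p = 9.08e-05; adjusted p = 0.208 with an estimated correlation). Also lower were 3 of 15 astrocyte genes, as GLUL (-0.22 ± 0.049), and 3 of 16 heat shock and hypoxia genes, as MT2A (-0.30 ± 0.062). The astrocyte list had camera adjusted p = 0.0338 (adjusted p = 0.35 with an estimated correlation) and the heat shock and hypoxia list 0.0112 (adjusted p = 0.35 with an estimated correlation).

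Some synaptic genes and some genes of upper and deep layers were higher in VFC. Of 20 postsynaptic scaffold genes, 10 were higher, as SHANK2 (0.27 ± 0.045) and LRRC7 (0.42 ± 0.087), and 11 adjusted over the list alone (median 0.16, camera adjusted p = 1.38e-06; adjusted p = 0.208 with an estimated correlation). Of 12 upper-layer genes 6 were higher, as PCDH8 (0.41 ± 0.075), and adjusted over the list alone 8 were higher and 1 lower (median 0.30, camera adjusted p = 0.00056; adjusted p = 0.209 with an estimated correlation). Of 17 deep-layer genes 3 were higher, as TSHZ2 (0.61 ± 0.085), and 5 adjusted over the list alone (median 0.078, camera adjusted p = 0.0187; adjusted p = 0.35 with an estimated correlation). Of 16 immediate early genes, JUN (0.22 ± 0.054) was higher (camera adjusted p = 0.0472; adjusted p = 0.411 with an estimated correlation). Glutamate receptors (4 of 12 higher, GRIK1 0.48 ± 0.083) and axon guidance genes (9 of 31 higher and 2 lower, ROBO1 0.30 ± 0.051, SEMA6A -0.37 ± 0.061) each had camera adjusted p = 0.00056. These had adjusted p = 0.159 and adjusted p = 0.208 with an estimated correlation. Monoamine and acetylcholine receptors (5 of 25 higher, HTR3A 0.75 ± 0.17) and cortical area patterning genes (6 of 22 higher and 1 lower, CDH8 0.51 ± 0.092) each had camera adjusted p = 0.00141 (adjusted p = 0.159 with an estimated correlation). Neuropeptides (4 of 11 higher, PDYN 0.77 ± 0.15) had camera adjusted p = 0.000942 (adjusted p = 0.208 with an estimated correlation), and GABA receptors (2 of 9 higher, GABRA5 0.45 ± 0.080) 0.0131 (adjusted p = 0.159 with an estimated correlation). Language-associated genes (3 of 11 higher, GNPTAB 0.24 ± 0.045) had camera adjusted p = 0.00218 (adjusted p = 0.208 with an estimated correlation). Meningeal and choroid plexus genes, markers of tissue outside the cortex, were higher for 4 of 11, as DCN (0.50 ± 0.11; camera adjusted p = 0.0011; adjusted p = 0.209 with an estimated correlation).

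Leaving out the 2 arrays, limma called more members higher among axon guidance genes (15), deep layers (6), monoamine and acetylcholine receptors (8), GABA receptors (5), immediate early (4) and language-associated genes (5), and more lower among astrocyte and heat shock genes (6 each). Of the respiratory chain genes, 9 were then lower over all genes and 15 adjusted over the list alone.

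Microglia (0 of 11 called by limma over all genes, median 0.091, camera adjusted p = 0.0172; adjusted p = 0.35 with an estimated correlation) and ribosomal proteins (0 of 19, median 0.072, 0.0112; adjusted p = 0.208 with an estimated correlation) read higher as lists (2 microglia genes called without the 2 arrays), with P2RY12 at 0.20 ± 0.060 (unadjusted p = 0.00594) in 5 of 5 animals. The 8 lists that did not pass were excitatory neurons (2 of 10 higher, camera adjusted p = 0.09), inhibitory interneurons (1 of 14 higher and 1 lower, 0.925), vascular cells (3 of 15 lower, 0.123), left-right body patterning (median of 6 genes -0.096, 0.238), ion channels (9 of 30 higher and 5 lower, 0.128), synaptic vesicle release (3 of 17 higher and 1 lower, 0.149), oligodendrocyte precursors (1 of 10 higher and 2 lower, 0.149) and interferon response (median of 6 genes -0.057, 0.338). Excitatory neurons did pass without the 2 arrays (camera adjusted p = 0.0325, and 0.187 with an estimated correlation) and without the 4 (0.0348). The mean of the oligodendrocyte and myelin list was lower in VFC than in M1C in 5 of 5 animals, for instance 7.77 against 9.34 log2 in animal 2. With that mean as covariate limma called 0 probe sets, with 2449 at an unadjusted p under 0.05, and MOBP, itself part of that mean, read 0.16 ± 0.093. With animal 1, 2, 4 or 5 left out limma called 1638, 999, 1203 or 1401 probe sets, of which 1530, 954, 1167 and 1328 were among the 2554.

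**Figure D3:**
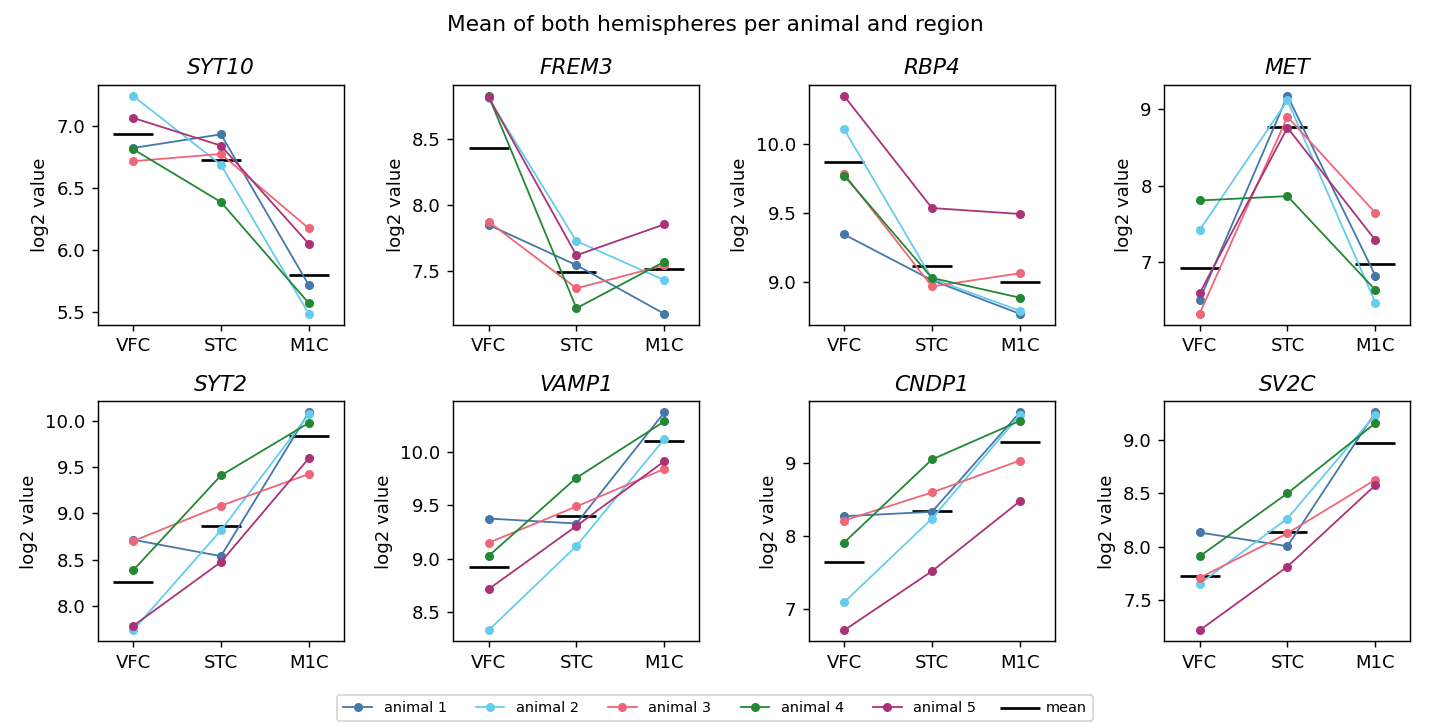
Log2 value (vertical) of 8 genes in the 3 regions, mean of both hemispheres per animal (5 coloured lines) and over animals (black bars). SYT10 reads 6.93 in VFC and 5.80 in M1C, and SYT2 8.26 and 9.84; MET is highest in STC at 8.76, as labelled.

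STC and M1C differed most at MET, a receptor tyrosine kinase, which read 8.76 ± 0.53 (SD, n = 5) log2 in STC and 6.97 ± 0.48 in M1C (1.79 ± 0.34, 3.45-fold, in 5 of 5 animals, limma adjusted p = 0.0254). Also higher in STC were the ephrin receptor EPHA3 (1.07 ± 0.21), SYT10 (0.93 ± 0.13), the opioid precursor PDYN (0.92 ± 0.15), the transcription factors TSHZ3 (0.76 ± 0.14) and TSHZ2 (0.69 ± 0.085), and AGT (0.73 ± 0.098). Lower in STC were SYT2 (-0.97 ± 0.20), CNDP1 (-0.94 ± 0.19), SV2C (-0.83 ± 0.11), GLRA1 (-0.81 ± 0.14, with an STC mean of 5.87, below the filter level) and HAPLN4 (-0.72 ± 0.16), each in 5 of 5 animals. Limma called 574 probe sets, 296 higher and 278 lower, and 3057 without the 2 arrays, of which 557 were among the 574. MET differed by 2.28 ± 0.23 without the 2 arrays.

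Of 15 large-axon and fast-firing genes, 6 were lower in STC, as VAMP1 (-0.70 ± 0.13), 12 without the 2 arrays and 12 adjusted over the list alone (median -0.32, camera adjusted p = 3.43e-09; adjusted p = 0.331 with an estimated correlation). Of 19 oligodendrocyte and myelin genes, CNDP1 alone passed over all genes, and 14 without the 2 arrays. Adjusted over the list alone, 3 passed as labelled and 18 without the 2 arrays. The list had a median of -0.35 as labelled (camera adjusted p = 1.1e-06, and 0.331 with an estimated correlation). Deep-layer genes were higher for 3 of 17, as HTR2C (0.58 ± 0.083), and axon guidance genes higher for 3 and lower for 1 of 31, as NRP1 (-0.47 ± 0.082). Leaving out the 2 arrays gave 8 higher and 1 lower among the former and 10 higher and 2 lower among the latter. Camera gave adjusted p = 0.000823 for deep layers and 0.000879 for axon guidance (adjusted p = 0.331 with an estimated correlation for both). Excitatory neurons read higher as a list (0 of 10 called by limma over all genes, 4 without the 2 arrays, median 0.12, camera adjusted p = 0.0278; adjusted p = 0.331 with an estimated correlation), with SLC17A6 at 0.66 ± 0.20 (unadjusted p = 0.00638) in 5 of 5 animals. Vascular genes were lower for 2 of 15, as ABCB1 (-0.33 ± 0.050), and for 5 without the 2 arrays (camera adjusted p = 0.00409; adjusted p = 0.331 with an estimated correlation). Lower in STC as lists were the respiratory chain (0 of 27 called by limma over all genes, 9 without the 2 arrays; median -0.094, camera adjusted p = 2.12e-05), astrocytes (2 of 15, 6 without; -0.14, 0.000432) and heat shock and hypoxia genes (0 of 16, 9 without; -0.11, 0.000823). Each had adjusted p = 0.331 with an estimated correlation; GLUL read -0.25 ± 0.049 and MT2A -0.18 ± 0.062 (unadjusted p = 0.0125) in 5 of 5 animals. Higher as lists were postsynaptic scaffold (0.080, camera adjusted p = 0.000432), neuropeptides (0.17, 0.000823), meningeal and choroid plexus cells (0.19, 0.00476; ISLR 0.44 ± 0.085), immediate early genes (0.11, 0.0171) and glutamate receptors (0.057, 0.0482). These had adjusted p = 0.331 with an estimated correlation, and immediate early genes adjusted p = 0.35. Camera called 14 lists as labelled and 18 without the 2 arrays. Read higher and called only without the 2 arrays were upper layers (camera adjusted p = 0.00702), language-associated genes (0.00751), monoamine and acetylcholine receptors (0.033) and cortical area patterning (0.0374). With an estimated correlation these had adjusted p = 0.192, 0.161, 0.135 and 0.133 there. The oligodendrocyte and myelin mean was lower in STC in 5 of 5 animals, and with it as covariate SYT10 (0.63 ± 0.073) and SLC39A12 (-0.52 ± 0.056) were called. With animal 4 or 5 left out limma called 256 or 180 probe sets (227 and 158 of them among the 574), with animal 1 left out SHISA6 and SLC39A12, and with animal 2 left out SLC39A12 and the unnamed 13813870, all named after their values were seen. Further, with no animal block limma called 0, with 2820 at an unadjusted p under 0.05.

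VFC and STC differed in fewer genes. FREM3, an extracellular matrix protein, read 8.44 ± 0.52 (SD, n = 5) log2 in VFC and 7.50 ± 0.20 in STC (0.94 ± 0.16, 1.92-fold, in 5 of 5 animals, limma adjusted p = 0.0405). CLIC6 (0.90 ± 0.14), RBP4 (0.76 ± 0.092), the kinase PRKCD (0.75 ± 0.076) and the fatty acid receptor FFAR4 (0.59 ± 0.048, adjusted p = 0.000601) were higher in VFC in 5 of 5 animals. MAS1 (-0.75 ± 0.13), STAMBPL1 (-0.52 ± 0.078), KCNH8 (-0.39 ± 0.069, with a VFC mean of 5.90, below the filter level), CHN2 (-0.35 ± 0.047) and DEPTOR (-0.33 ± 0.048) were lower in 5 of 5. Limma called 52 probe sets, 36 higher and 16 lower, and 159 without the 2 arrays, 46 of them among the 52. The largest difference among called probe sets was 1.92-fold as labelled, 4.21-fold without the 2 arrays and 4.41-fold without the 4. RASAL1 (0.52 ± 0.092) and KCNH8 did not pass without the 2 arrays, with differences of 0.50 ± 0.11 and -0.34 ± 0.084 (limma adjusted p = 0.0627 and 0.096; over all alternatives 0.0231 to 0.296 and 0.0414 to 0.292).

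Of 19 oligodendrocyte and myelin genes, 0 passed over all genes in limma (CNDP1 unadjusted p = 0.00312) and 15 were lower in VFC adjusted over the list alone (median -0.47, camera adjusted p = 1.68e-10; adjusted p = 0.546 with an estimated correlation). Large-axon and fast-firing genes read lower in VFC (median -0.24, camera adjusted p = 1.41e-05; adjusted p = 0.561 with an estimated correlation). Upper-layer genes read higher (median 0.12, camera adjusted p = 0.00958; adjusted p = 0.574 with an estimated correlation), with NECTIN3, a cell adhesion protein, called at 0.50 ± 0.061 in 5 of 5 animals; the list had a median of 0.11 without the 2 arrays and did not pass (camera adjusted p = 0.106; without the 4 arrays 0.0381; over all alternatives 0.00346 to 0.964). Microglia genes read higher in VFC (median 0.12, camera adjusted p = 0.0058; adjusted p = 0.561 with an estimated correlation), also without the 2 arrays but not without animal 3. Postsynaptic scaffold (0.070), monoamine and acetylcholine receptors (0.075) and glutamate receptors (0.066) read higher too (camera adjusted p = 0.00795 to 0.0246; adjusted p = 0.546 to adjusted p = 0.574 with an estimated correlation). These 3 calls were lost without the 2 arrays, and that of glutamate receptors without the 4. The oligodendrocyte and myelin mean was lower in VFC in 5 of 5 animals, and with it as covariate limma called FFAR4, FKBP1B, MET (-2.74 ± 0.26) and ADRA1A, named after their values were seen. With animal 1 or 4 left out limma called 82 or 24 probe sets (39 and 20 of them among the 52), with animal 2 left out PRKCD, FFAR4 and RBP4, and with animal 3 or 5 left out FFAR4 alone.

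**Figure D4:**
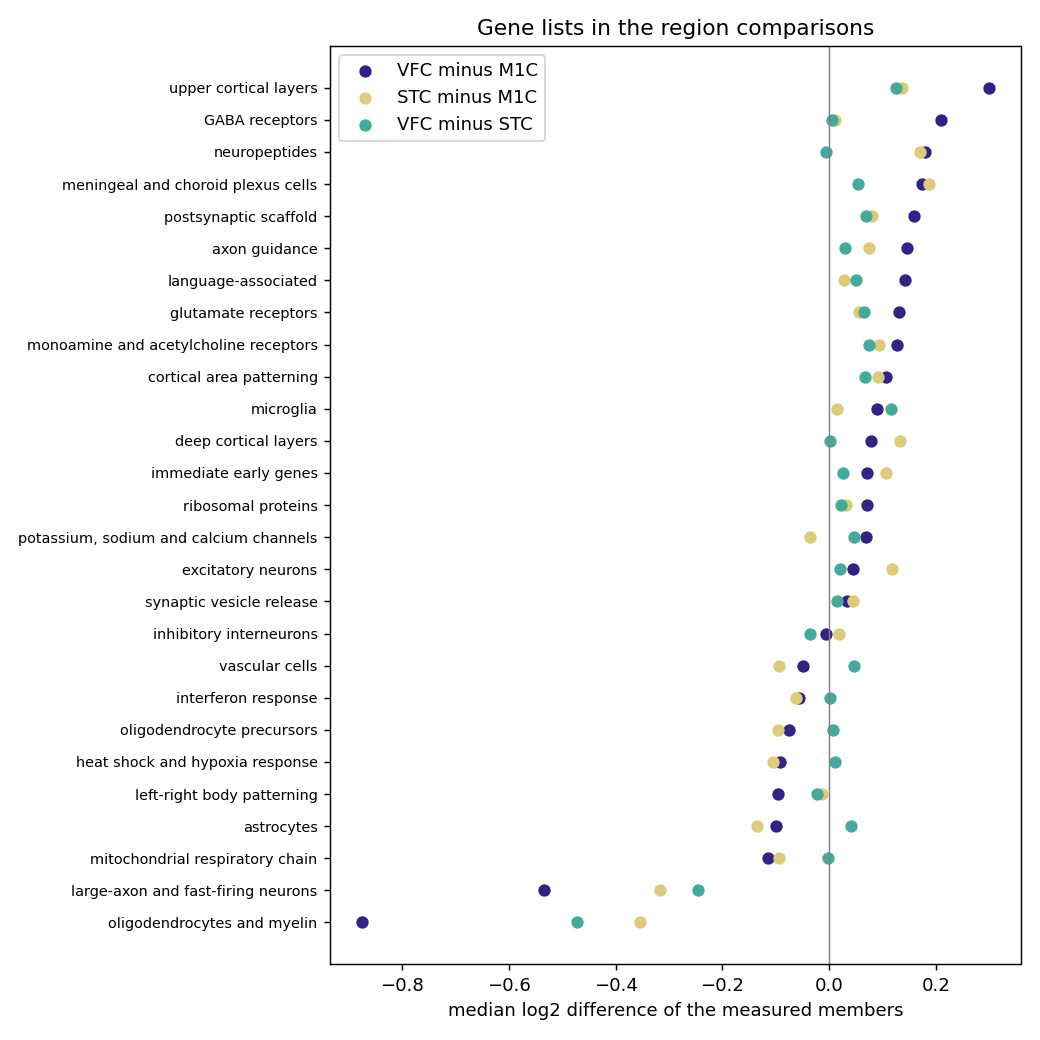
Median log2 difference of the measured members (horizontal) of the 27 tested gene lists (vertical) in the 3 region contrasts, 1 point per list and contrast. Oligodendrocytes and myelin lie lowest, at -0.88 in VFC minus M1C, and upper cortical layers highest, at 0.30.

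The share of variance by source summarises the design. Animal accounted for a median of 22.9% ± 4.65 (jackknife SE, n = 5) of the variance per probe set, where noise gives 12.1%. Region accounted for 8.73% ± 1.24 (noise 4.79%) and hemisphere for 1.30% ± 0.32 (noise 1.80%). The region by hemisphere term held 3.40% (noise 4.80%) and the animal by region term 20.3% (noise 26.5%). The noise levels are of simulated values with no animal or region effect. Since the sources divide a single total, a large animal share lowers the others, so a share under its noise level shows no absence of effect. The remainder, with 8 degrees of freedom like animal by region, held 20.2%. The shares include the 4 arrays in doubt and were not computed without these 4. Of the lists, blood had 2 of 13 genes measured and was not tested. Over the 7 contrasts camera called 68 list results at the preset correlation and 0 with an estimated correlation; without the 2 arrays 3 results in VFC vs M1C were called with an estimated correlation.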

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

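The tests of the arrays of animals 3 and 4, and the count without the 2 arrays for the large-axon genes, were chosen after the result was seen; the covariate test and the splits of the samples were not.

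The array labelled M1C left of animal 3 read 8.85 log2 on a male-high probe set, at which female animals 1 and 2 read 4.37 to 5.41. The array labelled STC right of animal 4 read 11.21 on a female-high probe set, at which male animal 5 read 4.60 to 5.70. On axes of 200 probe sets each from animal 3 to animal 4 and from STC to M1C, 4 of 4 positions lay nearer the end of the other array. Correct labels with unusual tissue are argued against by the smaller position towards the other animal (0.946), and a mixture of both RNAs by the share of the labelled sex's signal (at most 0.0271%). On the animal axis the arrays labelled M1C left of animal 3 and STC right of animal 4 lay at 0.965 and 0.0541. Arrays of animals 3 and 4 not in doubt lay at 0.060 to 0.101 and 0.894 to 0.982. On the region axis the 2 arrays lay at 0.0364 and 1.22, against 0.113 to 0.237 (STC) and 1.1 to 1.3 (M1C). Of the explanations weighed, an exchange of these arrays' labels is the only 1 that these values do not argue against. Sex-linked signal, animal position and region position each put both arrays with the label of the other. At which step an exchange would have arisen was not tested, and it stays a candidate explanation. The leading values keep the labels and so include both arrays. In STC vs M1C limma called 574 probe sets with them and 3057 without them.

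The array labelled STC right of animal 3 read 7.29 on the male-high probe set, and that labelled VFC left of animal 4 10.58 on the female-high one, each between the levels of pure arrays. On the axis from animal 3 to animal 4, 2 of 2 arrays lay between the ranges of the others (0.286 and 0.649, against 0.060 to 0.101 and 0.894 to 0.982). A wrong label alone is argued against by the share of the other sex's signal, at most 52.4%, where pure arrays hold at least 83.4% (male) or 80.5% (female). The shares of the labelled sex were 84.7% (STC right of animal 3, beside 35% of the other) and 107% (VFC left of animal 4, beside 52.4%), so that both add to over 100%, more than RNAs mixed in proportion give where signal follows amount. Whether it does was not tested, nor other partners, and a mixture of RNA of animals 3 and 4 stays open with that against it.

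Large-axon and fast-firing genes were lower in VFC than in M1C, as were oligodendrocyte and myelin genes (19 of 22 measured, 0 of 22 shared with another list; MOBP 9.82 against 10.99 log2). Without the 2 arrays 13 of 13 called members stay called, and the median went from -0.54 to -0.59. This is no test of the arrays out of place as the source. Of these arrays, only M1C left of animal 3 enters the VFC minus M1C difference. It lay at 0.0364 from STC to M1C, near STC, where these genes read lower than in M1C (median -0.32). That leaving it out would widen the difference could thus be foreseen. With the oligodendrocyte and myelin mean as covariate, 0 of 13 stay called; the median went from -0.54 to -0.21, 13 of 15 stay negative, and the median standard error rose from 0.084 to 0.12. More white matter in the M1C tissue cannot be told apart from a difference between the regions themselves, since the covariate differs by region in every animal. Region, as biology, stays open and untested.

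Single animals stood apart at 15 of 354 named results, where chance gives 17.7 (5%). Of the 10 in comparisons within 1 region, 9 fell on the left-right pairs that hold the 2 arrays. In STC these were animal 4 at SST (1.15), EGR2 (0.99) and HSPB1 (-0.91). In M1C they were animal 3 at ST18 (-1.26), HAPLN4 (-1.14), KCNA2 (-0.48), GRIN3A (0.51), VEGFA (-0.54) and NDUFB5 (-0.51). The others were H2BC9 in VFC (animal 4, 0.66), CNTNAP2 (animal 3, 0.10), NR4A2 (animal 1, -0.056) and NPY (animal 1, 0.016) over all regions, and GABRA5 (animal 5, 0.79) and ATP5F1C (animal 1, -0.35) in VFC vs M1C.

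Other splits of the samples were counted for each comparison, 100 each, the real one included. For the calls, 1 split was as large in VFC vs M1C (2554, highest other 3), 2 in STC vs M1C (574, highest other 1108) and 1 in VFC vs STC (52, highest other 47). Most of these splits do not part the regions of every animal, which the fit pairs, and the 16 splits that do are too few for a share under 0.05 (highest other 0 in each). The highest split in STC vs M1C is the real one with the M1C mean of animal 3 and the STC mean of animal 4 traded. It keeps both regions of animal 3 in the same group, and likewise those of animal 4. It thus parts 3 pairs, those of animals 1, 2 and 5, and does not test the labels of the 2 arrays. For probe sets at an unadjusted p under 0.05, chance cannot be excluded for hemisphere in VFC (78; 869, highest other 2266), STC (52; 1133, 3039), M1C (37; 1367, 3668), all regions (17; 1608, 2046) or the interaction (63; 912, 3135). A split tests only the left-right pairs that it parts, since the fit pairs the arrays of an animal. The highest in M1C (3668) parts 1 pair, that of animal 3. Its count therefore sets the array labelled M1C left of animal 3 against M1C right of animal 3 alone, and tests no grouping of animals. Among the 16 splits that part every left-right pair, 12, 9, 5 and 2 were as large for VFC, STC, M1C and all regions; the others differ by exchanging hemispheres or, for the region comparisons, regions within some animals.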

How the results depend on the processing

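Leaving out 2 or 4 arrays, and counting identical probe sets a single time, were chosen after the result was seen; the other alternatives were planned. Region calls depended on several settings, and causes were not tested unless given. In the order VFC vs M1C, STC vs M1C and VFC vs STC (2554, 574 and 52), limma called 833, 0 and 14 with no animal block (2820 at an unadjusted p under 0.05 for the 0) and 1676, 123 and 15 with no filter. It called 0, 2 and 4 with the oligodendrocyte covariate (2449 at an unadjusted p under 0.05 for the 0; SYT10 and SLC39A12; FFAR4, FKBP1B, MET and ADRA1A). On left arrays alone limma called 3 (AGT, SHISA6 and RBP4), 0 (2832 at an unadjusted p under 0.05) and 3 (PRKCD and a pair of unnamed probe sets). On right arrays alone it called 1147, 25 and 0 (2263 at an unadjusted p under 0.05). These genes were named after their values were seen. Of the 4 arrays in doubt, M1C left of animal 3 and VFC left of animal 4 are left arrays, and STC right of animals 3 and 4 are right arrays. The right VFC and M1C means hold none of them, so these counts do not compare the hemispheres. VFC vs STC gave 139 with the filter at the 60th percentile, 135 with trend and robust and 209 with 1 probe set per gene; STC vs M1C gave 924 with trend and robust. Without the 2 arrays STC vs M1C gave 3057 and VFC vs STC 159, and without the 4 arrays 2904 and 266.

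Hemisphere called 1 probe set in some settings. In VFC it was the unnamed 13594888 with the 60th percentile filter and with trend and robust. Over all regions it was SYT10 with repeated quantile normalization (adjusted p = 0.0423), with 1 probe set per gene (0.00335, fewer tests and prior degrees of freedom of 6.91 in place of 4.55) and with identical probe sets counted a single time (0.0461). Over all alternatives its adjusted p ranged from 0.00335 to 1 (no animal block), and was 0.824 without the 2 arrays. Leaving out 1 animal in turn gave 0 to 1 in VFC and over all regions (an unnamed probe set and NR4A2 without animal 1, named after their values were seen), 999 to 2272 in VFC vs M1C, 2 to 427 in STC vs M1C and 1 to 82 in VFC vs STC. With 1 animal left out, shares of variance ranged from 16.6% to 23.3% for animal (lowest without animal 5), 9.33% to 11% for region and 1.38% to 1.80% for hemisphere. The leading values for region (8.73%) and hemisphere (1.3%) lie below these ranges. Fewer arrays change the share that noise gives, and no noise level was computed for the smaller design. The ranges therefore do not measure dependence on single animals alone. Region held 7.02% with no filter.

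Of 68 list results called by camera, 0 were called with an estimated correlation. With the covariate 38 list results were called in all; of the 68, 27 stayed called, 33 were lost and 8 turned without a call. Without the 2 arrays 46 of the 68 stayed called, 19 were lost and 3 turned, and without the 4 arrays 49, 16 and 3. Of 126 called values of named genes, 124 stayed called with quantile normalization, 122 without the 2 arrays, 45 with no animal block and 3 with the covariate. With the covariate 10 turned in VFC vs M1C: EPHA3 -0.13, MOBP 0.16, ALDOC 0.069, GRIN3A -0.022, CHRM3 -0.0022, SST -0.076, CARTPT -0.050, CRYAB 0.095, NDUFA4 0.042 and LRRTM1 -0.064, none of them called; the cause was not tested. Probe sets with a mean below 6.04 log2 were left out of the leading values; the table holds no mark of which signals lie above background.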

Other observations

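The fit of differences between animals was chosen after the data were seen, and its genes were named after their values were seen. Animals differed at many genes, among them CNDP1, which also differed between regions. With region and hemisphere in the fit, and without the 4 arrays (26 left), limma called 6630 of 24292 probe sets (27.3%) between animals; arrays of 1 animal are not independent animals, and age and sex go with animal. COX16, an assembly factor of cytochrome c oxidase, read 8.37 log2 in animal 5 and 9.78 to 10.3 in the other 4. OBP2B, an odorant-binding protein, read 7.59 in animal 2 and at most 6.06 in the others, and TRAPPC3L 7.11 and 7.28 in animals 2 and 3 and at most 6.08 in the others. NQO1, a quinone reductase, read from 7.26 in animal 5 to 8.59 in animal 3, and CNDP1 from 7.59 to 8.91 in the same animals.

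The left minus right differences over all regions correlated across probe sets with the STC minus M1C differences of animals 1, 2 and 5. The r was 0.329 as labelled, 0.0155 without the 2 arrays and 0.0355 without the 4. On the axis from STC to M1C, the array labelled M1C left of animal 3 lay at 0.0364 and STC right of animal 4 at 1.22. As labelled, the left minus right differences of these animals thus hold part of an STC minus M1C difference. Probe sets are not independent replicates, and no test was run.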
